A study of Mus musculus with 5 samples.

How the data were processed

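RNA from the livers of adult C57Bl/6 mice was prepared with Trizol after storage in RNAlater, amplified as cDNA with a NuGEN Pico SL kit and labelled with biotin by a NuGEN Encore kit, per the labels' protocols. The deposited table holds 1 column of probe set intensity per array for 35556 probe sets, with values on a linear scale and medians between 32.5 and 33.9. Affymetrix Expression Console 1.1 is named per the submitters' processing notes; the summarisation, background correction and normalization settings are not given in the sources used here. The similar medians leave open how the arrays were brought to one scale. A method that draws arrays towards each other can hide differences shared by many genes, and one that does not can leave level-dependent shifts between arrays. Amplification of cDNA can also alter the ratio of dim to bright transcripts.

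Log2 of each intensity was taken, with no pseudocount, filter or further normalization. Samples were assigned to 3 control and 2 treated arrays from their labels. Probe sets were named through the platform's annotation, which can be old: 21218 probe sets had 1 gene symbol, 1881 had several, and 12457 were not listed there and are unnamed here. Of the symbols, 33 had no entry in the RefSeq gene table of assembly GRCm38.p6, and those kept the annotation's name. No coordinates were used. The 5 values of 540 probe sets repeated those of an earlier one, and all were kept in the tests.

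Treated and control arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, with 3 residual and 3.03 prior degrees of freedom), with Benjamini-Hochberg adjustment over all 35556 probe sets and a threshold of 0.05. An exact permutation test of 2 against 3 arrays cannot give a p under 0.1, so none is reported for single genes. Each of 42 gene lists, fixed before the data were examined, was tested with camera at a preset correlation of 0.01, over 1 probe set for each of 18820 genes, the one with the highest mean, with adjustment over the lists. Of 690 genes in the lists, 594 were measured; 1 list, of mitochondrially encoded genes, had no measured gene, and 41 were tested. Each list was also tested with an estimated correlation and with fry, its members were adjusted over the list alone, and its median was set against 10000 random lists matched on mean level, drawn from up to 100 genes on each side in the order of level. These random lists were drawn gene by gene, so they ignore correlation between a list's genes.

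The rule for the genes named was fixed at the same time. It takes, in each direction, the 10 with the largest change past the threshold or, since none passed, the 10 with the smallest p whose groups did not overlap. It also takes Csf1r, Csf1 and Il34, and up to 2 genes of smallest p from each list. Other list members given as examples, and the genes called with 1 probe set per gene, were chosen after their values were seen.

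The steps were tested on simulated data with the real control means and limma's moderated spreads. In 10 simulated comparisons of 35556 probe sets, each with 200 changed ones, 71.7% of 2-fold and 98% of 4-fold changes were recovered in the right direction, with 137 false calls in all. With a simulated shift of -0.3 on the log2 scale over 18820 genes, 30 of 30 shifted lists were found, and 5 of 380 unshifted ones were called. The simulated genes were independent of each other, which real genes are not. Moderated spreads also differ less between probe sets than the real ones. No shift with level was added, so the recovered shares can be too high for the real arrays. The alternatives tried were quantile normalization, centring on array medians, filters on dim probe sets, other sets of probe sets tested, other variance models, array weights, the replicate number as a block, leaving out each array (without 1 treated array the other is assumed to vary like the controls), other thresholds and other list tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.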

Results

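Liver gene expression was measured in adult C57Bl/6 mice that had been injected with either a rat IgG control or M279, an antibody against CSF1R. CSF1R is the receptor through which the growth factors CSF1 and IL-34 act on macrophages and monocytes. Each injection held 300 µg, and 3 injections a week were given into the peritoneal cavity for 6 weeks. The data were 3 control arrays and 2 arrays of treated liver, 1 liver sample per array, and each array gave an intensity for 35556 probe sets. Median intensity lay between 32.5 and 33.9 on all 5 arrays, and pairs of arrays correlated across probe sets with Pearson's r between 0.983 and 0.992 on the log2 scale. The 2 treated arrays correlated with each other at 0.9889. Treated replicate 1 correlated with the controls about as well, at 0.9868 to 0.9892, and treated replicate 2 less, at 0.9825 to 0.9842. The small number of arrays limits the precision: the median standard error (SE) of a log2 difference was 0.138. Nothing in the labels says how many animals the samples came from, so p-values measure only the spread between these samples.

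The question put to the data was how the antibody altered gene expression in the liver. The genes with the smallest p-values included higher values in treated liver for Marco, a scavenger receptor of macrophages (log2 difference of 1.34 ± 0.17, SE, 3 control and 2 treated arrays), and Angptl4, a secreted inhibitor of lipoprotein lipase (1.15 ± 0.13). Among the lower ones were Npas2, a transcription factor of the circadian clock (-1.43 ± 0.20), the muscarinic receptor Chrm3 (-1.29 ± 0.14), the phosphate transporter Slc34a2 (-1.26 ± 0.13) and the semaphorin receptors Plxnb1 (-1.11 ± 0.13) and Plxna2 (-1.03 ± 0.12). A second probe set of Plxnb1 differed by 0.17, in the other direction. The other genes with the smallest p among the lower ones were Rdh16f2 (-0.94), Aph1b (-1.16), Acpp (-1.04), Gca (-0.82) and Nab2 (-0.87). The remaining higher ones lay at low intensity in the controls, with log2 means such as 3.06 for Olfr705 and 3.70 for Lcn8, all under that of Marco (4.90), and their differences ran from 0.68 for Ceacam11 and Olfr705 to 1.27 for Mrgpra9.

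None of the 35556 probe sets passed an adjusted p of 0.05 in limma's two-sided test (0 higher and 0 lower in treated liver), and the smallest adjusted p was 0.175. Of these probe sets 12457 were not in the annotation, so what they measure is not known here. Of 56 higher and 284 lower probe sets with groups apart and at least 2-fold, 293 were unlisted. Without the 6616 numbered below the lowest listed one, the smallest adjusted p in limma was 0.0882, with 0 called. At an unadjusted p under 0.05 there were 3594 higher and 2965 lower probe sets, 18.4% of those tested. Both treated arrays lay outside the range of all controls for 14659 probe sets (41.2%), where chance gives 20%. When limma was fitted again on only 1 probe set per gene, 18820 in all, 5 genes were higher and 9 lower at an adjusted p under 0.05. This fit moderated the variances over these probe sets alone, so its p-values differ from those of the main fit. The SE values given here belong to the main fit. The 5 were Marco, Mrgpra9, Angptl4, A530064D06Rik and Olfr603, whose second probe set differed by only 0.087. The 9 were Cib3, Npas2, Chrm3, Slc34a2, Aph1b, Plxnb1, Acpp, Plxna2 and Rdh16f2. Other genes are therefore given as values, and fixed gene lists were tested as sets.

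**Figure D1:**
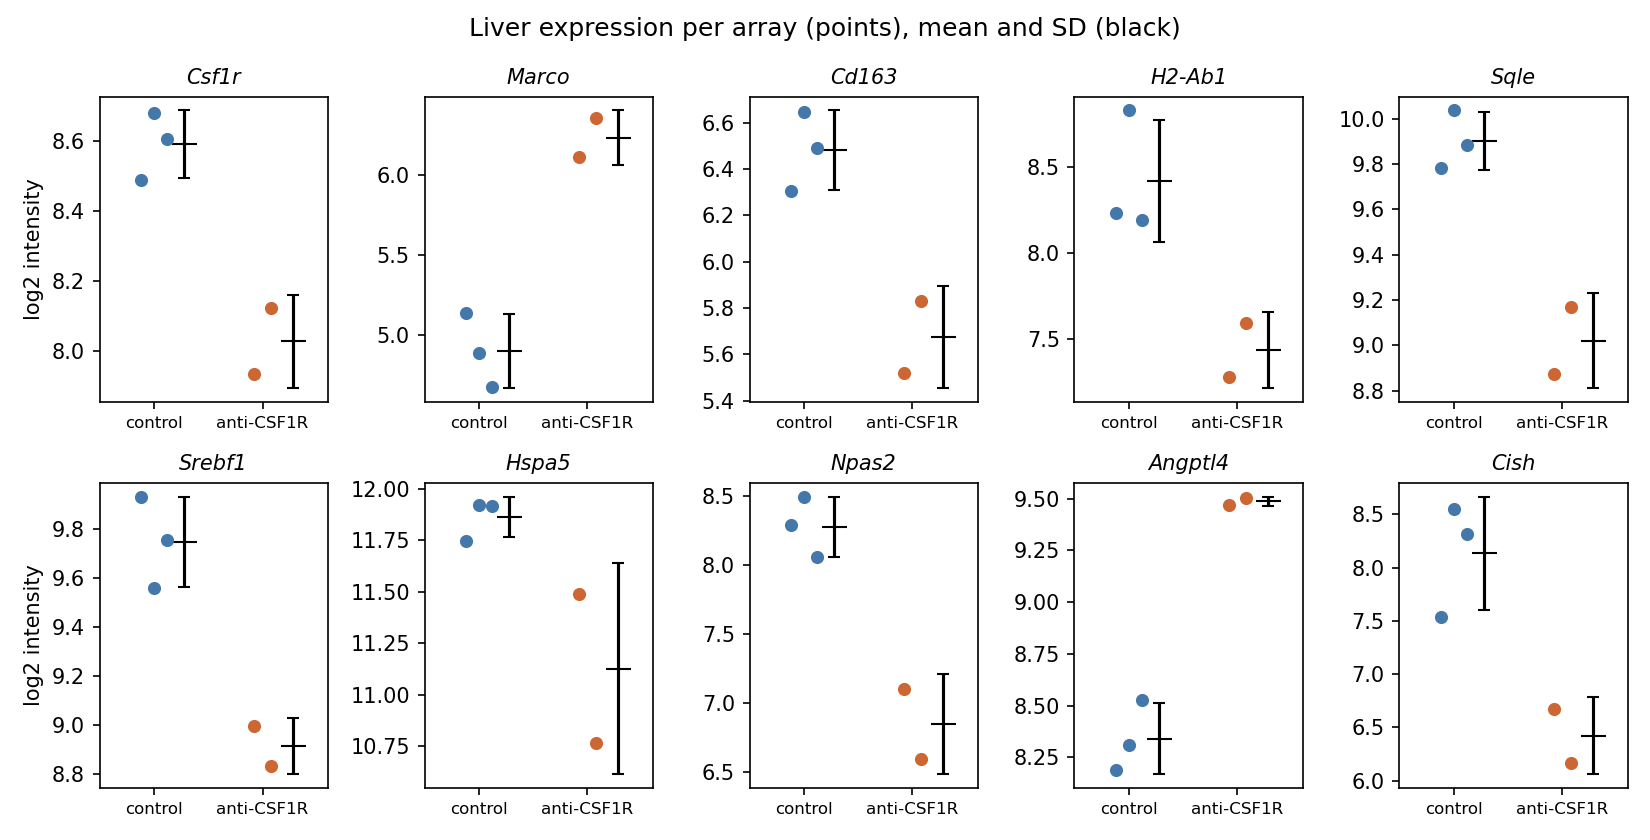
Log2 intensity (vertical axes) of 10 genes on the 3 control arrays (blue points) and the 2 anti-CSF1R arrays (orange points), with each group's mean and SD in black. Both treated arrays lie outside the range of the controls for each gene shown, as for Csf1r (log2 mean of 8.59 in controls and 8.03 in treated liver) and Marco (4.90 and 6.24).

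Csf1r itself was measured at a log2 mean of 8.59 ± 0.10 in controls (SD, n = 3) and 8.03 ± 0.13 in treated liver (SD, n = 2), a difference of -0.56 ± 0.12 (SE). Its adjusted p in limma was 0.191 over all probe sets and 0.0102 adjusted over the list alone, the list being the receptor and its ligands, and 0.0749 over the list of macrophage genes. The list of receptor and ligands had a mean of -0.31 (camera, adjusted p = 0.0967; adjusted p = 0.577 with an estimated correlation), with an adjusted p of 0.0204 without treated replicate 2 and 0.456 without treated replicate 1. The ligand genes Csf1 (-0.24 ± 0.16) and Il34 (-0.13 ± 0.30) differed by less than 2 SE. Il34 turned to 0.37 without treated replicate 1, and Csf1 was at -0.12 without treated replicate 2. The list of macrophage and phagocyte genes fell as a set, by a mean of -0.31 on the log2 scale, with 20 of its 22 measured genes lower (camera, adjusted p = 2.53e-05; adjusted p = 0.680 with an estimated correlation). Examples are the lysosomal protease Ctss (-0.60 ± 0.16), the pore-forming protein Mpeg1 (-0.57 ± 0.16) and the Fc receptor Fcgr4 (-0.71 ± 0.26). Without treated replicate 1, Ctss was at -0.38 and Fcgr4 at -0.39. None of the 22 passed, 0 adjusted over the list alone and 0 over all probe sets, while 11 had both treated arrays under all controls. The list's mean difference was -0.48 on treated replicate 1 and -0.14 on treated replicate 2. Without treated replicate 1 its adjusted p was 0.0951, and without control replicate 2, which had the highest values of the controls, its mean was -0.21.

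Markers of Kupffer cells, the resident macrophages of the liver, did not pass as a set: their mean difference was -0.06 and the median -0.12 (camera, adjusted p = 0.229; adjusted p = 0.812 with an estimated correlation). Of 18 measured markers, 1 was higher and 1 lower adjusted over the list alone, and 0 over all probe sets. These were Marco (1.34 ± 0.17), the largest rise in the list, and the haemoglobin scavenger receptor Cd163 (-0.80 ± 0.16). Marco pulled the list's mean up, but rank-based camera, on which a single gene weighs less, gave no call either (adjusted p = 0.156). Of the 18, 6 were higher and 12 lower. Widely used markers gave -0.25 ± 0.14 for Clec4f, -0.25 ± 0.22 for Timd4, -0.48 ± 0.18 for Adgre1 and -0.12 ± 0.18 for Vsig4, but 0.03 ± 0.15 for Cd5l, 0.13 ± 0.16 for Fcna and 0.16 ± 0.16 for Nr1h3. Each of these 7 values moved by over 1.5 times when 1 of the treated arrays was left out. Without treated replicate 1, Adgre1 was at -0.24 and Clec4f at -0.0954, while Timd4 (0.0422) and Vsig4 (0.12) turned positive, and without treated replicate 2, Cd5l (-0.15), Fcna (-0.0826) and Nr1h3 (-0.0126) turned negative. Cd5l turned negative without control replicate 1 too (-0.0346). The Kupffer cell list stood at -0.23 on treated replicate 1 and 0.10 on treated replicate 2. Without treated replicate 2 it passed, with an adjusted p of 0.00175 (camera, mean -0.225), and without treated replicate 1 its mean was 0.0963. The difference between the macrophage and Kupffer cell lists was not tested. The 4 genes of C1q and properdin, complement proteins made by macrophages, had a mean of -0.30 (camera, adjusted p = 0.0555; adjusted p = 0.737 with an estimated correlation), and properdin (Cfp, -0.50 ± 0.13) passed adjusted over the list alone. This list lay near the threshold and passed with arrays centred on their medians (adjusted p = 0.0454), a trend and robust variance model (0.0445) and array weights (0.0432). It also passed when control replicate 1 or 3 or treated replicate 2 was left out, with a mean of -0.546 and an adjusted p of 0.000642 in the last case. Without treated replicate 1 its mean was -0.0628 (adjusted p = 0.708). Monocyte markers had a mean of -0.04 over 12 genes (camera, adjusted p = 0.711), with Cx3cr1, a chemokine receptor of monocytes, at -0.57 ± 0.14. Lysosomal proteases and hydrolases fell as a set by a mean of -0.17, with 14 of 19 genes lower (camera, adjusted p = 0.0130; adjusted p = 0.427 with an estimated correlation), and 0 genes passed adjusted over the list alone. The call was lost without probe sets under the 25th percentile of level (adjusted p = 0.0914) or under the median (adjusted p = 0.413), while the mean stayed at -0.168.

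Genes of lipid synthesis were lower in treated liver. Cholesterol biosynthesis genes fell as a set by a mean of -0.35, with 17 of 20 genes lower (camera, adjusted p = 4.91e-07; adjusted p = 0.427 with an estimated correlation). Of these, 8 were lower adjusted over the list alone and 0 over all probe sets. They included squalene epoxidase (Sqle, -0.88 ± 0.14), Mvd (-0.86 ± 0.15), lanosterol synthase (Lss, -0.74 ± 0.11) and Srebf2, the transcription factor that drives the pathway (-0.34 ± 0.10). Fatty acid synthesis genes fell by a mean of -0.46, with 18 of 20 lower (camera, adjusted p = 2.56e-06; adjusted p = 0.613 with an estimated correlation). Of these, 9 were lower adjusted over the list alone and 0 over all probe sets, among them fatty acid synthase (Fasn, -0.71 ± 0.16), the lipogenic transcription factor Srebf1 (-0.83 ± 0.14), Thrsp (-0.64 ± 0.13) and Pnpla3 (-1.18 ± 0.34). The fatty acid list stood at -0.26 on treated replicate 1 and -0.66 on treated replicate 2. Genes of fatty acid oxidation and PPARA had a mean of 0.13 over 22 genes (camera, adjusted p = 0.392, 0.0122 with a mean of 0.295 without treated replicate 2, 0.444 with a mean of -0.0342 without treated replicate 1, and 0.00688 with a mean of 0.115 without probe sets under the median), and of them Angptl4 was higher adjusted over the list alone, while Acot1 was at 0.74 ± 0.20.

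Genes of the endoplasmic reticulum stress response fell as a set by a mean of -0.40, with 17 of 18 lower (camera, adjusted p = 2.56e-06; adjusted p = 0.427 with an estimated correlation). Adjusted over the list alone, 6 were lower and 1 higher, and 0 over all probe sets. The lower ones were mainly chaperones and folding factors, such as Hspa5 (-0.73 ± 0.22), Hyou1 (-0.72 ± 0.21) and Pdia6 (-0.47 ± 0.11), and the higher one was the pseudokinase Trib3 (0.84 ± 0.20). Without treated replicate 2, Hspa5 and Hyou1 were each at -0.37. Periportal hepatocyte genes fell by a mean of -0.27, with 12 of 13 lower (camera, adjusted p = 0.00124; adjusted p = 0.680 with an estimated correlation), and E-cadherin (Cdh1, -0.86 ± 0.21) and the mitochondrial aldehyde dehydrogenase Aldh1b1 (-0.71 ± 0.10) passed adjusted over the list alone. The periportal list stood at -0.15 on treated replicate 1 and -0.40 on treated replicate 2, with an adjusted p of 0.0386 without replicate 2, and it lost its call without probe sets under the median level (adjusted p = 0.0689, mean -0.27). Pericentral genes had a mean of -0.01 over 15 genes (camera, adjusted p = 0.779), with Tbx3 at 0.71 ± 0.20 and Slc1a4 at -0.66 ± 0.17, or 0.45 and -0.42 without the treated array that carried more of the difference. Genes of hepatocyte secreted proteins had a mean of -0.00449 over 14 genes (camera, adjusted p = 0.759), and passed only with cyclic loess (adjusted p = 0.00836, mean -0.139).

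Acute phase genes, which hepatocytes make in inflammation, fell as a set by a mean of -0.39, with 17 of 21 lower (camera, adjusted p = 0.000192; adjusted p = 0.427 with an estimated correlation), and 0 passed adjusted over the list alone. The call was lost without probe sets under the median level (adjusted p = 0.0683), where the mean was -0.403. Saa2, a serum amyloid A gene, had the largest difference among them (-2.97 ± 0.65), from a log2 mean of 9.63 ± 1.17 in controls (SD, n = 3) to 6.66 ± 0.52 in treated liver (SD, n = 2), and Lcn2 was at -0.98 ± 0.26. Genes of MHC class II antigen presentation fell by a mean of -0.41, with 8 of 9 lower (camera, adjusted p = 0.0219; adjusted p = 0.680 with an estimated correlation). H2-Ab1 (-0.98 ± 0.23) passed adjusted over the list alone, and the invariant chain gene Cd74 was at -0.81 ± 0.25. The class II list lost its call without treated replicate 1 (adjusted p = 0.376, mean -0.22) and, at its mean of -0.41, without probe sets under the 25th percentile of level (adjusted p = 0.0868). Inflammatory cytokines and chemokines had a mean of -0.33 over 22 genes (camera, adjusted p = 0.155). The mean was 0.028 without control replicate 2, and the list passed without control replicate 1 or 3 or treated replicate 2 (adjusted p of 0.0391, 0.00137 and 0.0258) but not without treated replicate 1 (adjusted p = 0.75, mean -0.242). On control replicate 2 the list stood 0.73 above the control mean, and the macrophage and class II lists stood 0.21 and 0.25 above it. The chemokine Ccl3 reached 9.83 there, against 6.26 and 4.71 on the other control arrays, and Il1b reached 8.08 against 6.78 and 5.14. Interferon-stimulated genes had a mean of -0.13 over 22 genes (camera, adjusted p = 0.168), with Stat2 at -0.62 ± 0.14. Their adjusted p lay between 0.0326 and 0.0491 when control replicate 1 or 3 or treated replicate 2 was left out. It was 0.614 without control replicate 2 (mean -0.0237) and 0.708 without treated replicate 1 (mean -0.0741).

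**Figure D2:**
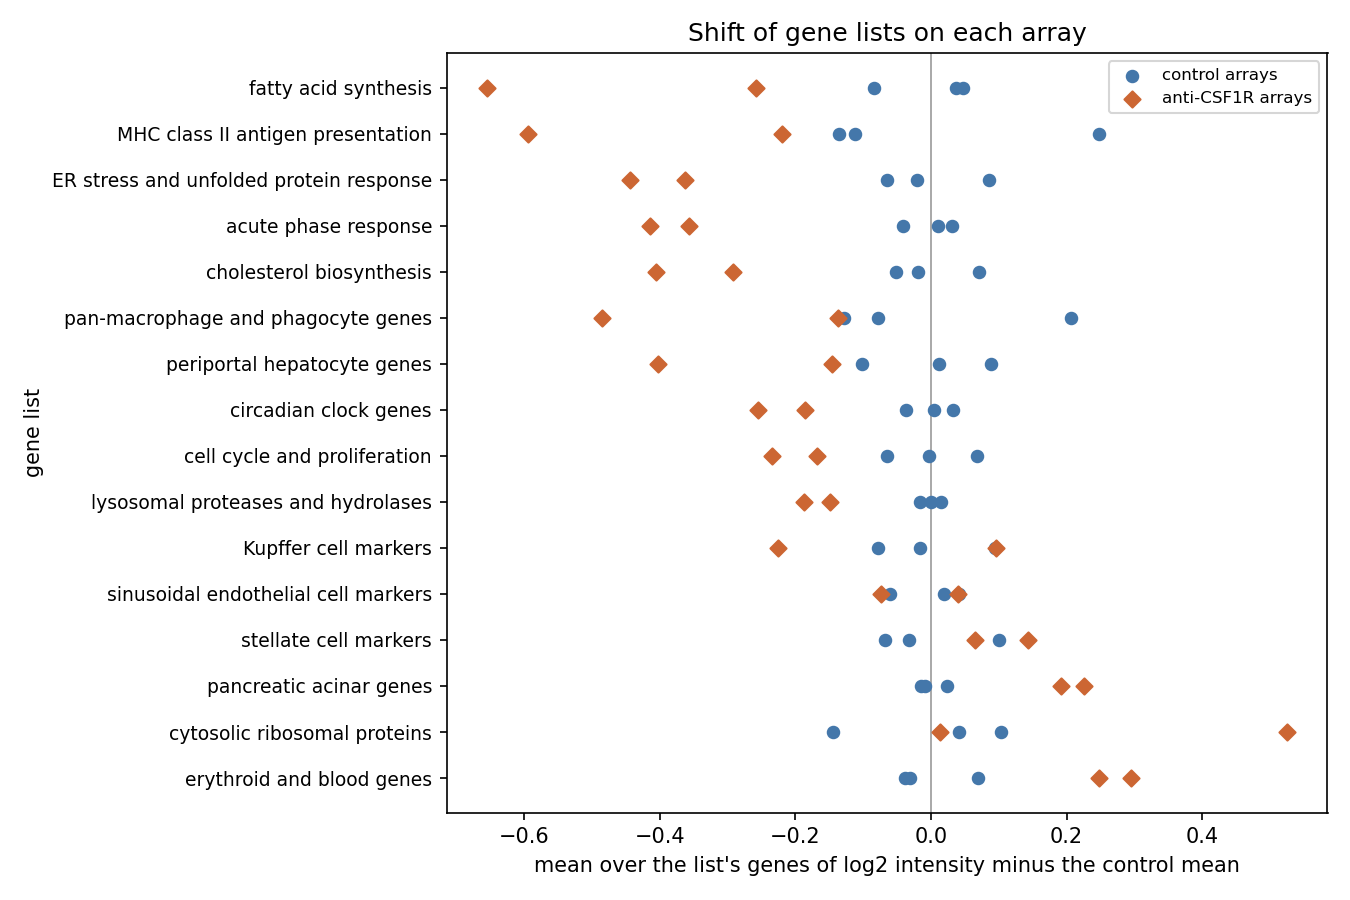
Mean over each gene list of log2 intensity minus the control mean (horizontal axis) on each control array (blue circles) and each anti-CSF1R array (orange diamonds), for the 13 lists that passed in camera with a preset correlation and for 3 cell type lists that did not. Cholesterol, fatty acid and endoplasmic reticulum lists lie under all controls on both treated arrays, while the Kupffer cell list lies at -0.23 on 1 treated array and 0.10 on the other.

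Circadian clock genes fell as a set by a mean of -0.22, with 11 of 16 lower (camera, adjusted p = 0.0449; adjusted p = 0.427 with an estimated correlation). The list's median of -0.193 lay at the 12.74th percentile of random lists matched on level, which gave -0.118. A shift with level could therefore account for the list's call. Dbp and Nr1d1 were left out of the list because their probe sets carry a second symbol, and these probe sets were at 1.58, 0.90 and -0.21. Adjusted over the list alone 4 were lower, namely Npas2, Arntl (-0.55 ± 0.15), Per2 (-0.47 ± 0.11) and Ciart (-0.49 ± 0.13), and 0 over all probe sets. Tef (0.41 ± 0.14) and Nr1d2 (0.40 ± 0.18) had higher values. The list lost its call when either of the treated arrays was left out, with an adjusted p of 0.0817 without replicate 1 (mean -0.256) and 0.0759 without replicate 2 (mean -0.186). The call was also lost at a mean of -0.22 in rank-based camera (adjusted p = 0.105) and without probe sets under the 25th percentile of level (adjusted p = 0.179) or the median (adjusted p = 0.761). It was lost at smaller means with quantile normalization (-0.124, adjusted p = 0.273) and cyclic loess (-0.137, adjusted p = 0.356). Arntl was at -0.35 without treated replicate 2, and Nr1d2 at 0.24 without control replicate 1. Cell cycle genes fell by a mean of -0.20, with 17 of 21 lower (camera, adjusted p = 0.00147; adjusted p = 0.427 with an estimated correlation), and the replication licensing gene Mcm2 (-0.63 ± 0.12) passed adjusted over the list alone. In the growth hormone list, which had a mean of -0.27 over 15 genes (camera, adjusted p = 0.172), Cish, an inhibitor of cytokine signalling, was lower adjusted over the list alone (-1.71 ± 0.33), and Onecut1 was at -1.51 ± 0.44, or -0.76 without treated replicate 2. The list's adjusted p was 0.0332 without control replicate 2 and 0.494 without treated replicate 2, where its mean was -0.118. Among genes of xenobiotic metabolism, with a mean of -0.09 over 20 genes (camera, adjusted p = 0.367; -0.154 to -0.0515 with adjusted p of 0.103 to 0.713 when 1 array was left out), the cytochrome P450 gene Cyp2b10 was lower adjusted over the list alone (-1.47 ± 0.24). The metallothionein Mt2 (0.97 ± 0.18) was higher and the cell cycle inhibitor Cdkn1a (-1.33 ± 0.31) lower among genes of gluconeogenesis and the fasting response, adjusted over that list alone. That list had a mean of -0.15 with 13 of 18 lower (camera, adjusted p = 0.229), and it passed without control replicate 3 (mean -0.255, adjusted p = 0.0427) and was at -0.0358 without treated replicate 2. Bile acid genes had a mean of -0.04 over 15 genes (camera, adjusted p = 0.501), with Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at -0.63 ± 0.18.

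Lists of other cell types did not pass. Sinusoidal endothelial markers had a mean of -0.02 over 15 genes (camera, adjusted p = 0.711), and stellate cell markers one of 0.10 over 13 genes (camera, adjusted p = 0.321), with Lrat, an enzyme of vitamin A storage, at 0.36 ± 0.12. The stellate list's median of 0.13 lay at the 99.83rd percentile of random lists matched on level. Its adjusted p in camera was 0.787 with an estimated correlation. A mean as large in size came from 3 of the 10 splits of the arrays, the real one included. The list passed with quantile normalization (adjusted p = 0.0274, mean 0.181), cyclic loess (adjusted p = 0.00836, mean 0.185) and without probe sets under the median (adjusted p = 0.00688), and its mean ranged from 0.0647 to 0.154 when 1 array was left out. Collagen and fibrosis genes had a mean of -0.06 over 19 genes (camera, adjusted p = 0.539). Neutrophil markers were at 0.19 over 13 genes (camera, adjusted p = 0.0579; 0.149 to 0.223 when 1 array was left out). They passed in camera without control replicate 1 (adjusted p = 0.0239), without probe sets under the 25th percentile of level (adjusted p = 0.0172, mean 0.203) and with array weights (adjusted p = 0.0432, mean 0.202). T and NK cell markers were at 0.07 over 19 genes (camera, adjusted p = 0.321; 0.01 to 0.148 when 1 array was left out). B and plasma cell markers were at 0.11 over 12 genes (camera, adjusted p = 0.392; 0.0723 to 0.156).

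The lists of ribosomal protein, pancreatic and blood genes passed upward as sets, with 0 of their genes passing adjusted over the list alone and 0 over all probe sets. Cytosolic ribosomal protein genes rose as a set by a mean of 0.27, with 24 of 24 higher (camera, adjusted p = 0.00312; adjusted p = 0.780 with an estimated correlation), but the list stood at 0.01 on treated replicate 1 and 0.53 on treated replicate 2, and without replicate 2 its adjusted p was 0.827. Pancreatic acinar genes rose by a mean of 0.21, with 11 of 11 higher (camera, adjusted p = 0.0291; adjusted p = 0.427 with an estimated correlation). Erythroid and blood genes rose by a mean of 0.27, with 6 of 6 higher (camera, adjusted p = 0.0404; adjusted p = 0.427 with an estimated correlation). The last 2 lists were dim, with mean log2 levels of 3.73 and 5.02, and both lost their call when either of the treated arrays was left out (adjusted p between 0.0585 and 0.0943), with means of 0.192 to 0.226 for the pancreatic and 0.247 to 0.295 for the erythroid list. The erythroid list lost it without control replicate 2 too (adjusted p = 0.07), and with quantile normalization both lists lost it, with adjusted p of 0.273 for the pancreatic (mean 0.107) and 0.0674 for the erythroid list (mean 0.215). Cyclic loess (adjusted p of 0.356 and 0.0591, means 0.0755 and 0.192) and leaving out probe sets under the 25th percentile (0.0625 and 0.111) ended both calls as well. Across all probe sets dim ones were higher and those of middle level lower on both treated arrays, by medians of 0.18 in the third of 10 bands of level and -0.154 in the seventh.

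**Figure D3:**
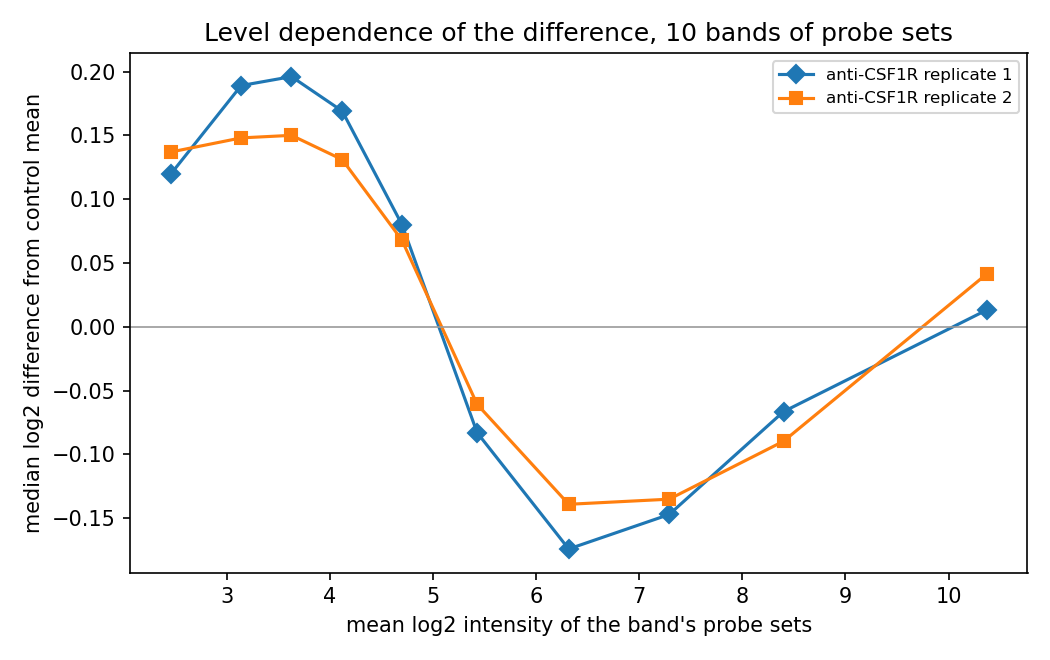
Median log2 difference from the control mean (vertical axis) in 10 bands of probe sets ordered by their mean log2 intensity (horizontal axis), for the 2 anti-CSF1R arrays. Both lines lie above 0 in the 5 dimmest bands and under it in bands 6 to 9, with 0.196 and 0.15 in band 3 and -0.174 and -0.139 in band 7.

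In all, camera with a preset correlation called 10 lists lower and 3 higher of the 41 tested. With an estimated correlation it called 0, and fry, which asks whether a list's genes move on balance one way, called 2, the lysosomal and pancreatic lists (adjusted p = 0.0338 each). Other splits of the 5 arrays into groups of 2 and 3 gave between 4 and 18 called lists, though a treatment difference can enter these splits too.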

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

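Cyclic loess, rank-based camera, a restriction to probe sets numbered from the lowest listed one on and matching on level were chosen after seeing the data. The count of called probe sets was 0 higher and 0 lower in limma under each setting except 2: with only probe sets of 1 gene symbol 3 were higher and 5 lower, and with 1 probe set per gene 5 and 9. Both settings moderated the variances anew over the probe sets kept. With the main fit's p-values, fewer tests alone could not give calls in either set, so the calls rest on the new variances. At an unadjusted p under 0.05 the 3594 higher and 2965 lower probe sets became 2560 and 2098 with quantile normalization and 4559 and 2395 with arrays centred on their medians. The counts were 2049 and 2348 with cyclic loess, and 656 and 2441 without probe sets under the median. Without 1 array they ran from 2126 (without control replicate 3) to 4224 (without treated replicate 1) higher and from 1867 (without treated replicate 2) to 3617 (without treated replicate 1) lower. The 13 called lists became 0 with an estimated correlation, 2 with fry, and between 8 and 17 without 1 array, the 8 without treated replicate 1; the cause was not tested. The macrophage list kept its mean of -0.311 but not its call with an estimated correlation (adjusted p = 0.68) or fry (adjusted p = 0.403), and ranged from -0.485 to -0.137 without 1 array. The Kupffer cell list ranged from -0.225 to 0.0963 without 1 array, and passed without treated replicate 2. The labels do not say whether the replicate numbers pair the samples. Deviations of same-numbered arrays correlated at 0.0268 and 0.0325, but only 2 pairs exist, which is too few to settle it. In a fit with the replicate number as a block, control replicate 3 has no treated partner and does not bear on the difference. Its list means therefore equal those without control replicate 3, and few residual degrees of freedom remain. With the replicate block 0 probe sets were called higher and 0 lower, and 17 lists in camera. Among these were C1q and properdin (adjusted p = 0.0249), gluconeogenesis (adjusted p = 0.0166), cytokines and chemokines (adjusted p = 8.27e-05, mean -0.566) and interferon-stimulated genes (adjusted p = 0.0462, mean -0.162). Il34 ranged from -0.633 to 0.365 without 1 array. Lists with no call either way changed sign, and the cause was not tested: B and plasma cell markers to -0.0089, dendritic cell markers to -0.107, female-biased genes to -0.231 and T and NK cell markers to -0.0564 without probe sets under the median, and female-biased genes to -0.0555 without those under the 25th percentile; bile acid genes to 0.00034, hepatocyte secreted proteins to 0.0333, iron genes to 0.0114, pericentral genes to 0.0256 and endothelial markers to 0.0209 with arrays centred on their medians. With quantile normalization, collagen genes went to 0.012, iron genes to 0.0172 and endothelial markers to 0.0172. With cyclic loess, dendritic cell markers went to -0.0328, female-biased genes to -0.0186, iron genes to 0.00394, endothelial markers to 0.0403, muscle genes to -0.000937 and T and NK cell markers to -0.0164. With the replicate block, pericentral genes went to 0.000516 and endothelial markers to 0.00343. Without 1 array, list means ranged from -0.111 to 0.0359 for bile acid genes, -0.212 to 0.0194 for cholangiocyte markers, -0.000656 to 0.145 for female-biased genes, -0.169 to 0.0403 for collagen genes, -0.0107 to 0.00358 for hepatocyte secreted proteins, -0.566 to 0.028 for cytokines, -0.105 to 0.0523 for iron genes, -0.181 to 0.054 for male-biased genes, -0.147 to 0.0402 for monocyte markers, -0.0127 to 0.058 for NRF2 genes, -0.121 to 0.0972 for pericentral genes, -0.0342 to 0.295 for PPARA genes and -0.0734 to 0.0396 for endothelial markers. Over all lists and settings, a list lost its call in its own direction 50 times and gained one 30 times, among these hepatocyte secreted proteins with cyclic loess (-0.139). Named genes passed the threshold in 21 cases, all of them with only probe sets of 1 gene symbol or 1 probe set per gene. Signal over background could not be set for the arrays, so the values of dim genes have no stated floor.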

Other observations

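The genes outside the lists and the checks of causes in this part were chosen after the results were seen. The gene lists were fixed before, and their camera results repeated here were planned. Cish was named by the rule fixed before. Among genes outside the lists, Bcl6, a transcriptional repressor in liver, was at 1.36 ± 0.39 (log2 difference ± SE, limma adjusted p = 0.207), while Cish was at -1.71. Rgs16, a regulator of G protein signalling, was at 1.53 ± 0.46 (limma adjusted p = 0.212). A probe set shared by Sphk2 and Dbp, which cannot be given to either gene, was at 1.58 ± 0.43, and of those shared by Nr1d1 and Thra, 1 was at 0.90 and the other at -0.21. The male-biased list had a mean of -0.08 over 14 genes, and Xist stayed between 3.10 and 3.34 on all arrays. Small nucleolar RNAs, 63 probe sets, stood at 0.525 on treated replicate 2 and -0.0481 on treated replicate 1, and ribosomal protein genes at 0.53 and 0.01.

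The real split gave 6559 probe sets with an unadjusted p under 0.05, and the highest of the other splits gave 2936, so 1 of the 10 splits, the real one, gave as many. For genes called with 1 probe set per gene the values were 14 and 1, and again 1 of 10 splits gave as many. For called lists they were 13 and 18, and 5 of 10 splits gave as many. With 10 splits no share under 0.05 can be had. The shift with level that both treated arrays had in common can also add to the count of 6559. The split of control replicates 2 and 3 against the rest gave the 18 lists and the 2936 probe sets, and that of control replicates 1 and 2 gave 15 lists. Both kept the 2 treated arrays in 1 group, so a difference between treated and control liver can enter them. Splits with 1 treated array in each group gave up to 14 lists. No other split is free of the treatment, so they give no reference for chance alone.

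Lipid synthesis and chaperone lists were lower in camera with a preset correlation. They had no call with an estimated correlation or with fry (adjusted p in fry of 0.0594, 0.253 and 0.0594 for the cholesterol, fatty acid and endoplasmic reticulum lists). Random lists matched on level gave a median of -0.0416 at the lowest for the 3 lists, against measured medians of -0.31, -0.39 and -0.48, and with the shift of genes of like level taken off each list still lay under all controls on both treated arrays, which argues against an array-wide shift with level as the whole cause. A single deviating array is argued against too, since the treated array nearest to the controls still stood at -0.258, under all controls. Clock genes that peak in late phase stood 0.624 above those of early phase (0.386 and 0.863 on the treated arrays, against -0.24 to 0.235 on the controls). The gap lay in the 5 early genes, with a mean of -0.64, while the mean of the 9 late genes was -0.0159. A different clock phase or feeding time at cull may contribute. This cannot be told apart from the treatment because the labels give no time of cull. An effect of the antibody on the liver stays open as well and was not tested apart from these.

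The macrophage list was lower (adjusted p = 0.68 with an estimated correlation, and 0.0951 without treated replicate 1) while the Kupffer cell list had no call (0.00175 without treated replicate 2), a difference that was not tested. Of 28 endothelial and stellate markers 27 lay above the macrophage mean, but that mean was taken up for being low, so the count says little. These markers stood 0.35 above macrophage genes, by 0.536 on treated replicate 1 and 0.164 on treated replicate 2, where controls ran from -0.211 to 0.196. Their own means of 0.0512 and 0.0271 on the treated arrays lay inside the controls' -0.0636 to 0.0681. On treated replicate 1 these values argue against a smaller share of all cells other than hepatocytes as the whole cause. On treated replicate 2 the gap lay within the controls, so that array cannot decide it. The treated array nearest to the controls stood at -0.137, just under the lowest control at -0.128, so a single deviating array cannot be told apart from a treatment effect with 2 treated arrays. Matched random lists gave a median of -0.099 against -0.27, but once the shift of genes of like level was taken off, the list stood at -0.389 on treated replicate 1 and -0.0376 on treated replicate 2, within controls that ran from -0.149 to 0.197, so a shift with level could account for the second array. Loss or altered state of macrophages through CSF1R blockade is a hypothesis that these data leave untested.

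Dim probe sets were higher on both treated arrays. The 979 olfactory receptor genes, which are dim and not known as liver genes, had a median of 0.176, and other genes of their level one of 0.178, which is consistent with an array-wide shift with level. The pancreatic, erythroid and neutrophil lists reached at most the 94.06th percentile of matched random lists, so the same shift could account for their higher values. The neutrophil list did pass without probe sets under the 25th percentile of level, though (camera, adjusted p = 0.0172). Whether amplification, hybridisation or the authors' normalization made the shift was not tested, and cells of these types stay open.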
